A study of Mus musculus with 4 samples.

How the data were processed

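The series holds 4 droplet single-cell RNA libraries, 1 for each combination of 2 genotypes (wild-type, WT, and Ndufa4-deficient, written KO below) and 2 organs (subcutaneous B16-F10 melanoma tumour and spleen). Per the labels, the mice were males of the C57BL/6 background, aged 8 weeks, and organs were taken on day 18 after tumour implantation. Tumour cells were sorted for the pan-leukocyte marker CD45, and spleen cells for CD45 together with the myeloid marker CD11b. Equal cell numbers from 3 mice per genotype were pooled before loading, per the series design text, while the protocol in the labels allows up to 4 mice. Per the labels, 16000 cells were loaded per lane of a 10x Chromium 3' v3.1 kit.

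The deposited values are whole-number counts of unique molecular identifiers (UMIs) per gene and cell barcode, not normalized. Per the file headers, the count matrices were written by Cell Ranger 6.0.0, while the submitters' processing notes name Cell Ranger 3.1 and Seurat 3.1.4 and 3.1, with the builds mm10 and GRCm38. The annotation version is not given in the sources used here. Each deposited matrix lists the same 32285 genes and between 4798 and 8107 barcodes, so the authors had already separated cells from empty droplets. Barcodes and gene names, both deposited as text lists, were used only as names. No cell annotation was used, and cells were not assigned to single mice within a pool.

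Cells were kept with at least 200 genes, at least 500 UMIs and at most 10% of UMIs from mitochondrial DNA. Doublets were called per library with Scrublet in scanpy 1.11.5 and left out. Where the automatic threshold marked under 0.5% or over 15% of cells, the cells with the highest scores were marked instead, at 0.8% per 1000 barcodes. The automatic threshold marked 5.44% of the spleen WT cells and 2.80% of the spleen KO cells. It marked 0.124% of the tumour WT cells and 0.0430% of the tumour KO cells, so the scores' top 3.83% and 4.90% were left out there. The mitochondrial limit removed 752 tumour WT and 1462 tumour KO barcodes, and 563 spleen WT and 827 spleen KO barcodes.

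The cells of each organ were clustered over both genotypes, without integration. Counts were scaled to 10000 per cell and logged, 2000 variable genes were chosen with the library as batch, and 30 principal components and 15 nearest neighbours fed Leiden clustering at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9). Genes of the interferon, MHC, respiratory complex, mitochondrial DNA, cell cycle and immediate early lists, and mitochondrial, ribosomal, haemoglobin, immunoglobulin and T cell receptor genes, were left out of the variable genes. The neighbour graph was rewritten after first values had been seen, so that clusters did not depend on the processor, and a different random seed of the Leiden step was added as an alternative. Clusters were named from 24 fixed marker lists, and every class name below means cells like that type. A cluster was left unnamed if it had under 3 detected markers, a low UMI count with no own marker among its top 10 genes, or at least 3 more markers of another class than of its own there. That last limit was set after the clusters had been seen. It left 1 spleen cluster unnamed, with 0.309% of WT and 1.36% of KO cells, led by macrophage genes beside natural killer cell genes. Unnamed cells made up 0.0517% of the WT and 0.542% of the KO tumour cells.

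T cells were clustered again among themselves to separate CD8, CD4 and regulatory cells. A subcluster was named by the share of its cells with a UMI of Cd8a or Cd8b1 (at least 0.7), or of Cd4, Foxp3 or Trdc (at least 0.5 each), limits set after the subclusters had been seen. In the tumour, cluster 3 of the T cells had no own marker and 1 marker of another class among its top 10 genes, so the total T cell share is not compared. CD8 and regulatory T cells are compared as subsets, and tumour CD4 T cells for their share only, since the WT library held 44 of them. A class was compared for expression where both libraries held at least 50 of its cells. Monocytes and macrophages of the tumour were compared together as mononuclear phagocytes, the main comparison, and also apart.

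For each class, the UMIs of each gene were summed over its cells in a library and scaled to the class total as CPM, which is not a deposited unit. The KO/WT ratio is given on the log2 scale, so positive values mean higher in KO, with an exact 95% conditional binomial interval in square brackets. Levels have exact Poisson intervals, shares have exact (Clopper-Pearson) binomial intervals, and differences of shares have Newcombe intervals in percentage points. A gene with 0 UMIs was given a bound from a floor of 3 counts over the class. With 1 pooled library per genotype and organ, no test between genotypes was possible, no p-value was computed, and no difference has a replicate check. All intervals cover counting error only, not the spread between mice, and those of genes and lists not the spread between cells.

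Genes entered lists and rankings if they reached at least 20 CPM in 1 of the 2 libraries compared and at least 100 UMIs over both. Among genes at least 1.5-fold apart, those named were the 10 highest and 10 lowest in tumour mononuclear phagocytes, and the 5 highest and 5 lowest in every other class. They were ranked by the interval bound nearest to no difference. Ndufa4, gene models without a name, the gene classes named above and markers of other cell types were left out of this ranking. Up to 4 members of each list were named by the same ranking, and Ndufa4, Ndufa4l2, AA467197 (the mouse C15orf48), Ifnb1, Ifng, Cxcl9, Cxcl10, Arg1, Nos2 and Cd274 always. The 28 gene lists covered type I and type II interferon responses, MHC class I and class II presentation, nucleic acid sensing, nuclear subunits of complexes I to V, mitochondrial DNA genes, the mitochondrial and integrated stress response, NRF2 and redox genes, glycolysis, hypoxia, inflammatory mediators, suppressive and repair macrophage genes, lysosome and phagocytosis, cholesterol synthesis, cytotoxic effectors, T cell exhaustion, naive and memory T cells, immature neutrophil granules, tumour neutrophils, cell cycle, immediate early genes, C57BL/6 substrain genes and genes of the sex chromosomes. Some genes that this rule takes are not reported here. Only 3 listed symbols (Mx1, Mx2 and Ahsp) had no match among the gene names. Each list with at least 4 measured members has its median log2 ratio, an interval from 1000 Poisson redraws of its counts, and its median's percentile among 10000 random lists of the same size matched on mean expression in 10 bins. That percentile describes these libraries and is no test. Members at least 1.5-fold apart were counted. Interferon list UMIs per cell were compared after each cell was thinned to 2000 UMIs, leaving out shallower cells.

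Library totals ran from 46499361 to 63560706 UMIs. Totals of the compared classes ran from 507859 UMIs (spleen WT T cells) to 27440115 UMIs (spleen WT monocytes), and this sets the width of the intervals. The procedure was tested on data simulated from the tumour mononuclear phagocytes with all 32285 genes run and 200 genes changed. The simulated counts were independent Poisson draws, the model that the intervals assume. The test therefore checked the calculation only, not the spread between cells or mice. Intervals held the true ratio for 95.3% of unchanged and 95.4% of changed genes. The size rule passed 0% of unchanged genes, 51.3% of those changed 1.5-fold, and 100% of those changed 2-fold or 4-fold. Of 100 unchanged lists, 97.0% fell inside the middle 95% of random lists, and a raised list reached a percentile of 100.

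The groups, comparisons, gene and marker lists, naming rule and 14 of the 17 alternative settings were fixed before the data were examined. The 3 added later were a mitochondrial limit of 20%, no mitochondrial limit, and the other Leiden seed. The planned ones covered stricter cell filters, doublets kept, Leiden resolutions of 0.5 and 2.0, listed genes allowed in the clustering, other scalings, equal weight for each cell, thinning and other expression floors. Shares of T cell subsets among all T cells were computed but are not reported, for the reason given above. Coordinates are 1-based, from GENCODE M21 on GRCm38, matched by gene identifier for all 498 named genes. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.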

Results

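The data were UMI counts from 4 single-cell libraries, 1 WT and 1 Ndufa4-deficient (KO) library from each of 2 organs, B16-F10 melanoma tumours and the spleens of tumour-bearing mice. B16-F10 is a melanoma line of C57BL/6 mice that grows in animals of that strain. Ndufa4 is a small subunit of cytochrome c oxidase (complex IV), the last enzyme of the mitochondrial respiratory chain. The tumour libraries held 4798 WT and 6122 KO barcodes with 47754169 and 63560706 UMIs. The spleen libraries held 8107 WT and 7789 KO barcodes with 57272311 and 46499361 UMIs. After filtering, 3865 WT and 4428 KO tumour cells and 7120 WT and 6757 KO spleen cells were kept. The kept tumour cells were unequal in depth, with medians of 7217 UMIs in WT and 10360 UMIs in KO, whereas the spleen medians were 4692.5 and 4370 UMIs. Each library pooled several mice and stood alone for its group, so no difference below could be set against the spread between animals. The comparisons followed the series labels: which immune cells were present, and what they transcribed, with and without Ndufa4, in the tumour and in the spleen.

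Ndufa4 transcripts were nearly absent from the KO immune cells of both organs and present in the WT cells. In tumour mononuclear phagocytes Ndufa4 (ENSMUSG00000029632, chromosome 6: 11900292 to 11907497, minus strand) stood at 279 CPM in WT (5751 UMIs) and 6.56 CPM in KO (95 UMIs), a log2 ratio of −5.41 [−5.72, −5.12]. The ratio was −7.19 [−7.60, −6.81] in tumour CD8 T cells, −6.93 [−7.81, −6.16] in tumour natural killer (NK) cells, −6.20 [−7.17, −5.38] in regulatory T cells and −5.13 [−5.59, −4.71] in dendritic cells. Tumour neutrophils gave few Ndufa4 counts, 171 UMIs in WT and 1 UMI in KO, with a ratio of −4.81 [−10.12, −2.31]. Tumour B cells held 282 and 12 UMIs, a ratio of −4.09 [−5.06, −3.27]. In the spleen, monocytes held 7515 UMIs in WT and 12 UMIs in KO (−8.02 [−8.98, −7.22]), and NK cells 1875 and 4 UMIs (−9.90 [−11.78, −8.54]). KO spleen neutrophils, red pulp macrophages and T cells held 0 UMIs of Ndufa4 against 506, 333 and 131 UMIs in WT. Against a floor of 3 counts this made Ndufa4 at least 221-fold, 80.7-fold and 109.8-fold lower. On the log2 scale these bounds were −7.79, −6.33 and −6.78. With each cell thinned to 1000 UMIs they were −5.285, −3.91 and −3.68, tumour neutrophils, then with 0 KO UMIs, had a bound of −0.95, and the ratio of mononuclear phagocytes was −4.98. At Leiden resolution 0.5 the bound of red pulp macrophages was −3.25. A residue of 42.5 CPM was left in KO tumour phagocyte cluster 10, against 396 CPM in WT. The few barcodes with melanoma genes, 54 in the WT and 24 in the KO tumour, held Ndufa4 at 1611 and 1284 CPM, a log2 ratio of −0.33 [−0.46, −0.20]. The WT barcodes of this class also held 106728 erythroid marker UMIs against 2 in KO, and their median mitochondrial shares were 0.436% and 2.901%, so the class was not alike in both libraries. The implanted line did not come from the mice, so its Ndufa4 was outside the labelled genotype. Which part of the gene was removed is not given in the sources used here.

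**Figure D1:**
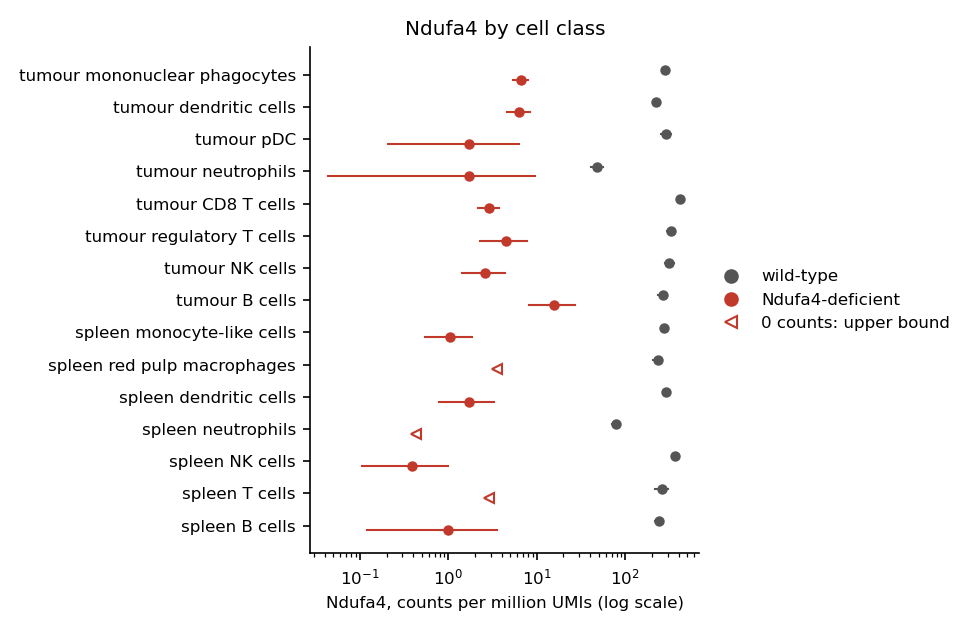
Ndufa4 level in CPM (log axis) in the main cell classes of the tumour and spleen, WT and KO, with exact 95% Poisson intervals for counting error. WT classes of both organs sit far above their KO partners. Melanoma-like barcodes (1611 and 1284 CPM) are not drawn.

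The KO tumour held fewer neutrophils and mononuclear phagocytes and more CD8 T cells and NK cells, as shares of its CD45-sorted cells. Neutrophils, short-lived granulocytes, made up 26.3% of WT cells (1017 cells) and 3.57% of KO cells (158 cells), a difference of −22.7 points [−24.2, −21.3]. Mononuclear phagocytes made up 34.8% and 21.5%, a difference of −13.3 points [−15.2, −11.4]. CD8 T cells, the cytotoxic T cells, made up 9.60% (371 cells) and 27.8% (1230 cells), a difference of 18.2 points [16.6, 19.8]. NK cells, innate cytotoxic lymphocytes, made up 3.86% (149 cells) and 16.9% (747 cells), a difference of 13.015 points [11.8, 14.3].

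Among the phagocytes, macrophages made up 28.9% of WT and 13.9% of KO tumour cells, and monocytes 5.90% and 7.61%. The monocyte share differed by 1.71 points [0.628, 2.79], and this ranged from −0.32 points with a mitochondrial limit of 20% to 7.56 points with listed genes allowed in the clustering. Regulatory T cells made up 3.67% and 5.71% (2.04 points [1.13, 2.95]), and other CD4 T cells 1.14% and 4.13% (2.99 points [2.32, 3.69]). The latter were a subcluster in which 74.45% of cells held a UMI of Cd4, 20.26% of Cd8a or Cd8b1, and 4.85% of Foxp3. Dendritic cells, which present antigen to T cells, made up 7.19% and 8.49% (1.30 points [0.136, 2.45]), and this turned to −0.015 points without a mitochondrial limit and to −0.956 points [−2.36, 0.409] among all cells except neutrophils. Plasmacytoid dendritic cells made up 2.02% and 2.06%, a difference within counting error (0.037 points [−0.585, 0.646]). B cells made up 4.53% and 1.87% (−2.65 points [−3.44, −1.90], and −4.23 points without a mitochondrial limit), and γδ T cells 0.207% and 0.971%. Shares within a sort must sum to the whole, so the classes were also compared among all cells except neutrophils. There, mononuclear phagocytes made up 47.2% and 22.3%, CD8 T cells 13.03% and 28.8%, and NK cells 5.23% and 17.5%, while regulatory T cells made up 4.99% and 5.93%, a difference within counting error (0.939 points [−0.152, 1.99]). The CD45 gate and the pooling of equal cell numbers set these denominators, so the shares do not give cells per gram of tumour.

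**Figure D2:**
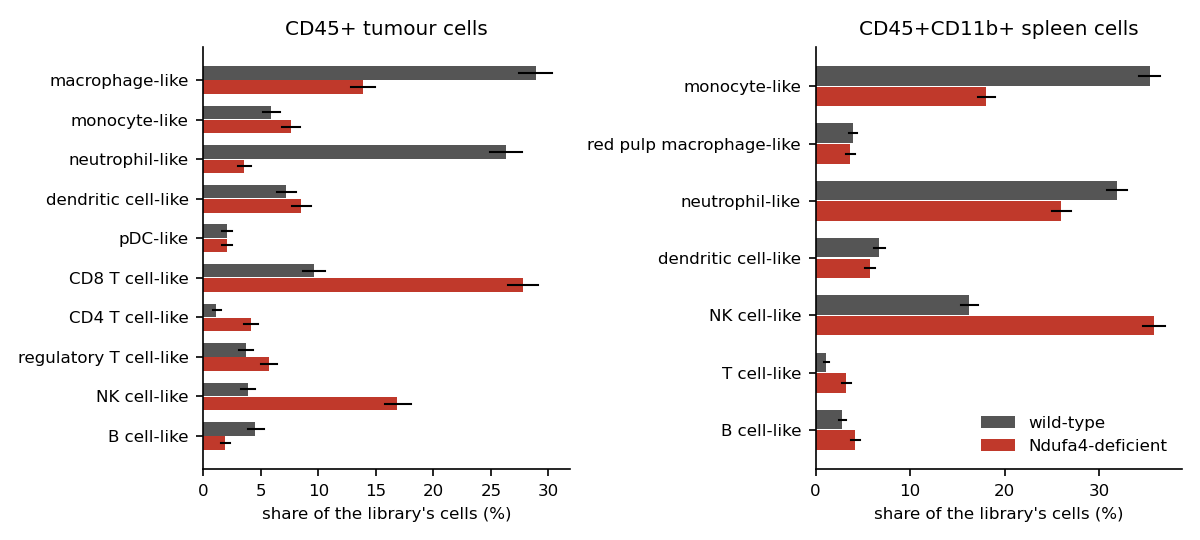
Share of each cell class among the kept cells of a library in percent, WT and KO, for the tumour (CD45 sort) and the spleen (CD45 and CD11b sort), with exact 95% binomial intervals for counting error. In the tumour, neutrophils are at 26.3% and 3.57% and CD8 T cells at 9.60% and 27.8%; in the spleen, NK cells are at 16.3% and 35.8%.

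The main comparison asked what tumour mononuclear phagocytes, the monocytes and macrophages, transcribed without Ndufa4. It was chosen because the series title names tumour-associated macrophages and interferon signalling. Over the pooled cells, interferon-response genes were higher in KO as a group, and genes of hypoxia, glycolysis and suppressive or tissue-repair macrophages were lower. These pooled ratios were not corrected for the mix of phagocyte clusters, which is given below. Cxcl9, which encodes a chemokine that attracts activated T cells, stood at 230.1 CPM in WT and 1242 CPM in KO (log2 2.43 [2.39, 2.48]). Arg1, which encodes the arginine-degrading enzyme arginase, stood at 1711 and 254 CPM (−2.75 [−2.80, −2.70]). The 1344 WT and 951 KO phagocytes had median depths of 13578 and 13720 UMIs.

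Of the 33 measured genes of the type II interferon list, those chiefly induced by interferon gamma, 31 were at least 1.5-fold higher in KO and 0 lower, with a median log2 ratio of 1.95 [1.86, 2.02]. Guanylate-binding protein genes led it: Gbp2 stood at 188 and 1050 CPM, Gbp4 at 20.2 and 150.2 CPM, and Gbp2b at 2.18 and 41.4 CPM (4.25 [3.81, 4.72]). Calhm6 was also higher, at 2.59 [2.46, 2.72]. Of the 66 genes of the type I interferon list, 54 were at least 1.5-fold higher and 1 lower, with a median of 0.94 [0.92, 0.98]. They included Zbp1 (1.64), Oas3 (1.64) and the chemokine Cxcl10 (1.39 [1.34, 1.44]). Antigen presentation moved with them. In the MHC class I list 18 of 21 genes were at least 1.5-fold higher (median 1.08 [1.02, 1.14]), with the peptide transporter gene Tap1 at 1.57, Tapbpl at 1.53 and the class I transactivator Nlrc5 at 1.43. In the MHC class II list 7 of 8 genes were higher (median 0.99 [0.98, 1.00]), with the class II transactivator Ciita at 56.5 and 196 CPM (1.79), H2-DMa at 1.16 and H2-Ab1 at 1.00. Each of these 4 medians lay above all 10000 random lists. Among 13 nucleic acid sensing genes 2 were higher and 1 lower (median 0.23 [0.14, 0.34], percentile 97.9), led by Samhd1 (1.80 [1.76, 1.84]) and Tmem173, which encodes STING (1.15).

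Ly6a and Ly6i, cell surface genes of the Ly6 family, were also higher, at 2.45 [2.40, 2.504] and 2.61 [2.48, 2.74]. Ppfia4, a gene of the liprin family (chromosome 1: 134296783 to 134332928), showed the largest ratio of the named genes, from 7 UMIs in WT to 504 UMIs in KO (6.68 [5.63, 8.00]). Dnase1l3, which encodes an extracellular nuclease, stood at 3.92 [3.47, 4.41] and the nuclear receptor gene Nr4a2 at 2.74 [2.56, 2.93]. Klrk1, the NKG2D receptor gene usual in NK and CD8 T cells, was at 2.72 [2.53, 2.92]. It belongs to the cytotoxic effector list, in which 4 of 6 measured genes were higher and 1 lower (median 1.91 [1.76, 2.01], percentile 100), among them Klrd1 (2.41), Nkg7 (2.29) and Ccl5 (1.54). That median was 0.37 when each cell was thinned to 1000 UMIs, Nkg7 stood at 1.44 with doublets kept and Klrd1 at 1.67 with equal weight for each cell. Markers of T and NK cells were higher in the same cells: summed T cell markers stood at 30.5 CPM in WT and 126 CPM in KO, and NK cell markers at 10.4 and 46.5 CPM. The naive and memory T cell list had a median of 0.67 [0.61, 0.72] over 4 genes (percentile 99.4), and the T cell exhaustion list 0.06 [−0.01, 0.15] over 5 genes (percentile 55.1).

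**Figure D3:**
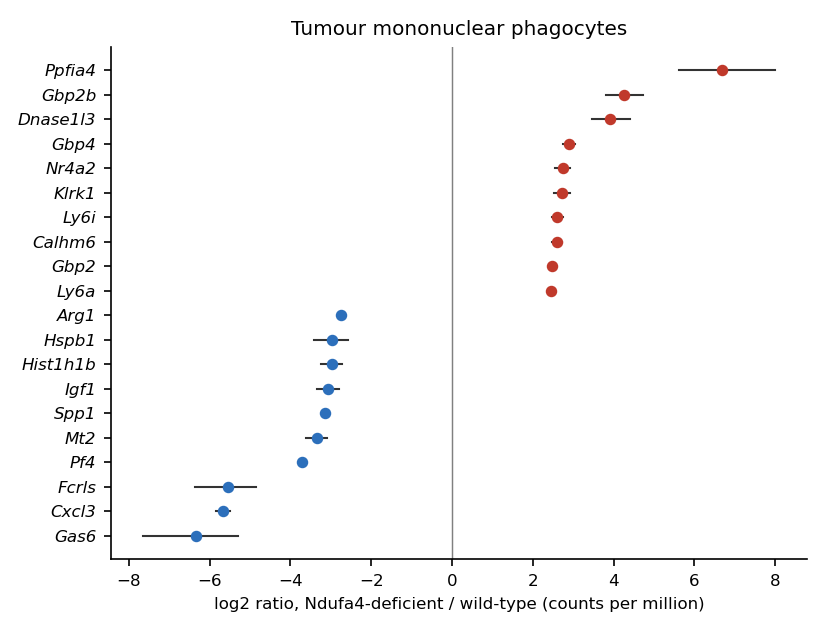
Log2 KO/WT ratio of the named genes in tumour mononuclear phagocytes, with exact 95% intervals for counting error. Interferon-response genes such as Gbp2 (2.49) and Gbp2b (4.25) lie right of 0 and Arg1 (−2.75), Spp1 (−3.13) and Cxcl3 (−5.66) lie left of it.

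The genes lower in KO phagocytes were led by Cxcl3, a neutrophil-attracting chemokine gene, at 947 CPM in WT and 18.7 CPM in KO (−5.66 [−5.84, −5.49]). Spp1, which encodes osteopontin, stood at 2646 and 301 CPM (−3.13 [−3.18, −3.09]). Of the 20 suppressive and repair macrophage genes measured, 15 were at least 1.5-fold lower and 0 higher, with a median of −1.12 [−1.25, −1.05]. Besides Spp1 and Arg1 these included the metalloelastase gene Mmp12 (−2.46) and the scavenger receptor gene Stab1 (−2.34). Of 18 hypoxia genes 15 were lower and 0 higher (median −1.04 [−1.10, −0.96]), including Hilpda at 504 and 167 CPM (−1.59), Adm (−1.78), Ero1l (−1.68) and Egln3 (−1.63). In the glycolysis list 8 of 16 genes were lower (median −0.59 [−0.61, −0.56]), with the glucose transporter gene Slc2a1 at −1.10. Lysosome and phagocytosis genes were lower in 7 of 23 cases (median −0.38 [−0.40, −0.32]), among them the cathepsin genes Ctsl (−1.65) and Ctsd (−1.57), Cd63 (−1.68) and the efferocytosis receptor gene Mertk (−1.48). Cell cycle genes were lower in 11 of 16 cases (median −0.79 [−0.94, −0.65]), with Stmn1 at −2.21 and Mki67 at −1.57 (−0.80 and −0.67 with thinning to 1000 UMIs). NRF2 and redox genes had a median of −0.45 [−0.49, −0.34], with 5 of 13 lower and the haem oxygenase gene Hmox1 at 1239 and 531 CPM (−1.22). Mitochondrial and integrated stress genes had a median of −0.43 [−0.53, −0.39], with 3 of 10 lower, Gdf15 at −1.83 and Ddit3 at −0.79. None of the members of these last 3 lists was 1.5-fold higher, and all 7 medians of this paragraph lay below the percentile of 0.1.

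Gas6 (−6.34 [−7.66, −5.29]), Fcrls (−5.56 [−6.37, −4.85]) and the growth factor gene Igf1 (−3.06 [−3.33, −2.80]), all typical of resident macrophages, were lower too. So were Pf4 at 1119 and 85.3 CPM (−3.71 [−3.80, −3.63]), the metallothionein gene Mt2 (−3.34 [−3.61, −3.09]), the histone gene Hist1h1b (−2.98 [−3.24, −2.74]) and the small heat shock gene Hspb1 (−2.98 [−3.42, −2.57]). Summed neutrophil markers were 865 CPM in WT and 249 CPM in KO phagocytes, and summed platelet markers, which share no gene with the macrophage list, 166 and 12.3 CPM. Inflammatory mediators went both ways, 5 of 22 higher and 7 lower with a median of 0.01 [−0.06, 0.11] (percentile 45.2): Il27 was higher (2.59 [2.23, 2.96]) and the chemokine genes Cxcl1 (−2.28) and Cxcl2 (−1.74 [−1.78, −1.71]) were lower. With thinning to 1000 UMIs, Gas6 stood at −4.96, Igf1 at −2.01, Il27 at 1.501 and Cxcl1 at −0.95. With equal weight for each cell, Igf1 stood at −2.31 and Hist1h1b at −2.34. Immediate early and dissociation genes had a median of 0.54 [0.51, 0.56] (percentile 100), with 8 of 20 higher and 2 lower, Fosb at 1.69, Btg2 at 1.55 and the heat shock gene Hspa1b at −1.74. Cholesterol synthesis genes had a median of 0.26 [0.18, 0.37] (percentile 96.5). Tumour neutrophil genes stood at −0.63 [−0.68, −0.56] (percentile 0.03) and immature neutrophil granule genes at 0.24 [0.23, 0.27] (percentile 90.7).

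Genes of the respiratory chain other than Ndufa4 differed little. None of the nuclear subunit genes measured, 36 of complex I, 4 of complex II, 9 of complex III, 11 of complex IV and 17 of complex V, was 1.5-fold apart. Their medians were 0.03, −0.03, 0.12, 0.05 [0.01, 0.09] and −0.01, within the middle 95% of random lists, and the complex IV median turned to −0.031 when each cell was thinned to 1000 UMIs. The 13 mitochondrial DNA genes had a median of 0.10 [0.08, 0.11], with none 1.5-fold apart, and 87 ribosomal protein genes a median of −0.02. Nos2, the inducible nitric oxide synthase gene, stood at 88.3 and 88.5 CPM (0.00 [−0.10, 0.11]). The checkpoint ligand gene Cd274 was at 0.39 [0.32, 0.47]. AA467197, the mouse counterpart of the human gene for an NDUFA4 paralog, was at −0.22 [−0.30, −0.15]. Ndufa4l2 was too rare for a firm ratio, with 57 UMIs in WT and 18 UMIs in KO (−1.15 [−2.00, −0.36]). Ifnb1, the interferon beta gene, gave 42 and 19 UMIs, a difference not detectable at this depth (−0.63 [−1.4965, 0.18]). Ifng gave 19 and 54 UMIs in these cells.

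Clusters held different parts of the phagocytes in the genotypes. Cluster 1, led by Cfb and Cxcl9, held 28.1% of WT and 45.4% of KO phagocytes, cluster 5, led by Arg1 and Thbs1, 37.9% and 11.0%, the monocyte cluster 6 17.0% and 35.4%, and cluster 10, led by Ccl8 and Vcam1, 17.0% and 8.10%. The macrophage share of phagocytes differed by −18.5 points, by −46.6 with listed genes allowed in the clustering, and by −8.63 with a mitochondrial limit of 20%. Within them, the type II list medians were 1.496, 1.78, 1.67 and 1.65, and the type I list medians 0.76, 0.94, 0.81 and 0.93. The KO cells of cluster 10 were shallower (median 4327 against 10665 UMIs), and the median of all its genes lay at −0.14. Macrophages as a whole had medians of 2.08 for type II and 0.99 for type I. Arg1, Mmp12, Hmox1, Pf4, Spp1 and Nos2 were among the top genes of cluster 5, and Igf1, Fcrls and Gas6 among those of cluster 10. Only the interferon lists were also computed with the KO clusters weighted to the WT mix. The pooled ratios of these genes and of the lists lower in KO therefore include any effect of the mix.

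**Figure D4:**
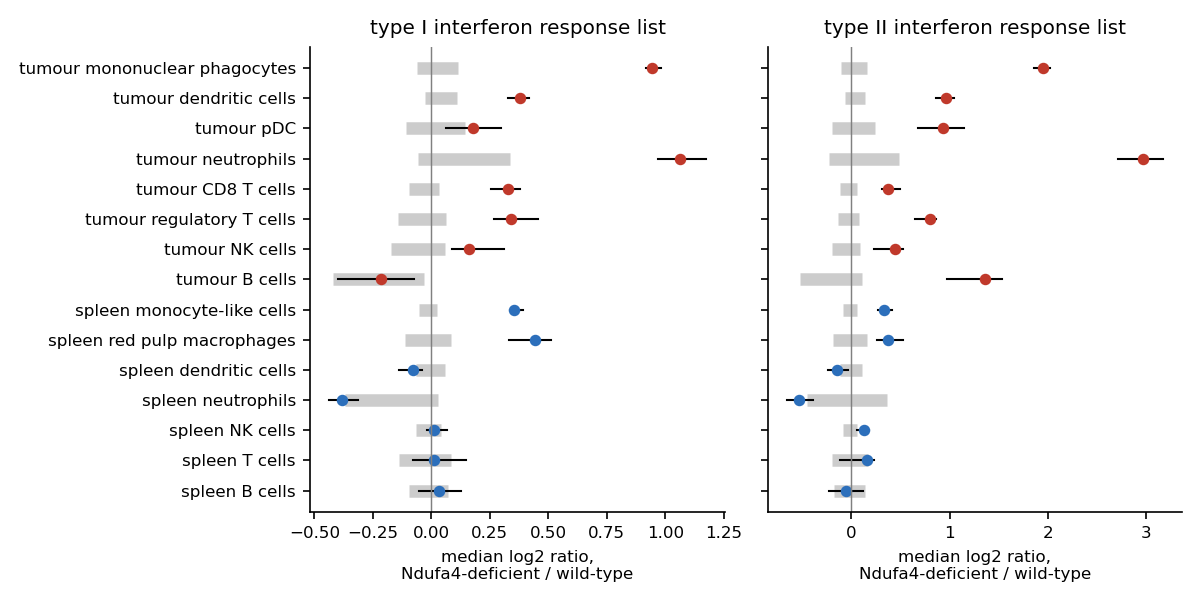
Median log2 KO/WT ratio of the type I and type II interferon lists in the main compared classes (red for tumour, blue for spleen), with the counting interval as a black line and the middle 95% of 10000 matched random lists as a grey bar. Tumour macrophages, tumour monocytes and dendritic cell subsets are not drawn apart. Of the classes drawn, tumour neutrophils (type II, 2.97) and mononuclear phagocytes (1.95) lie farthest to the right, while the spleen classes lie between −0.53 and 0.44.

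The type I interferon difference was spread over most phagocytes. After thinning to 2000 UMIs per cell, which left out 56 WT and 30 KO cells, the mean was 18.4 type I list UMIs per WT cell and 34.03 per KO cell (log2 ratio 0.89 [0.86, 0.91]). The medians were 12 and 30 UMIs, and without thinning the means were 141 and 264 UMIs. Of the KO cells, 34.5% lay above 37 UMIs, the 90th percentile of the WT cells, against 9.94% of the WT cells themselves. Type II list UMIs averaged 3.84 and 14.2 per cell, with medians of 2 and 10, and 50.5% of KO cells lay above 9 UMIs, against 9.39% of WT cells.

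**Figure D5:**
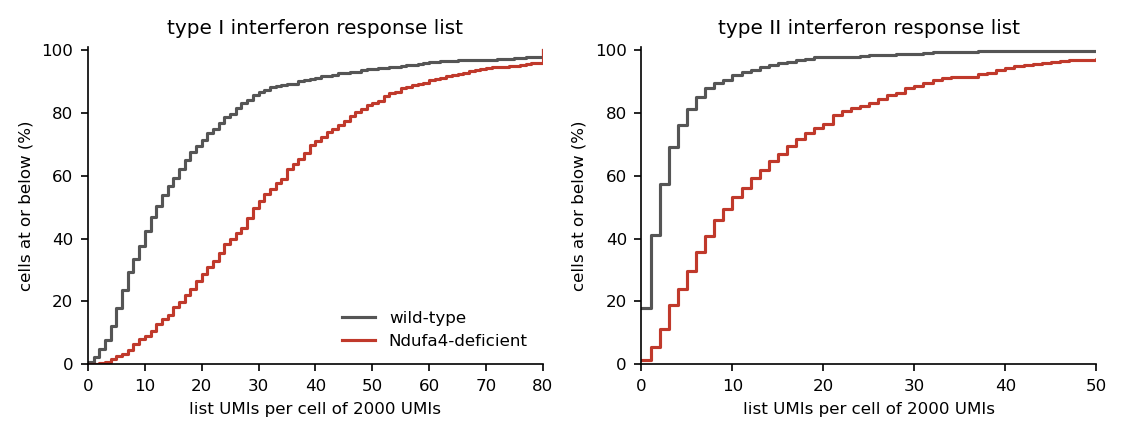
Cumulative percent of tumour mononuclear phagocytes by their number of type I interferon list UMIs after thinning each cell to 2000 UMIs (80 or more pooled), WT and KO. The KO curve lies to the right of the WT curve over most of the range, with medians of 30 and 12 UMIs.

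Lymphocytes of the KO tumour showed higher Ifng and immediate early genes. In CD8 T cells, Ifng, the gene of interferon gamma, stood at 168 CPM in WT and 469.5 CPM in KO (1.48 [1.38, 1.58]). In NK cells it stood at 40.1 and 153 CPM (1.94 [1.47, 2.45], but 4.55 with thinning to 1000 UMIs). Granzyme B (Gzmb), a killing protease of cytotoxic granules, was at 479 and 1264 CPM in NK cells (1.40 [1.26, 1.54]). In CD8 T cells, 6 of 19 cytotoxic effector genes were at least 1.5-fold higher and 2 lower (median 0.43 [0.32, 0.50], percentile 100), with Klrk1 at 1.62 and Klrd1 at 1.31 and with Klrg1 at −1.65 (−0.83 with thinning to 1000 UMIs). In NK cells the same list had 5 of 18 genes higher and 2 lower, with a median of 0.02 [−0.04, 0.11] (percentile 62.2).

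Immediate early genes, which respond to stimulation and also to tissue dissociation, were higher in 12 of 18 cases in CD8 T cells (median 1.08 [0.93, 1.23]) and in 10 of 18 cases in NK cells (0.91 [0.73, 1.11]), both at a percentile of 100. Named genes in CD8 T cells were Ifitm1 (4.205 [3.48, 5.05]), Styk1 (3.66 [2.899, 4.54]), Rgs2 (3.05 [2.81, 3.30]), Fos (3.00 [2.64, 3.37]) and Dapl1 (3.26 [2.59, 4.03]) on the higher side. On the lower side they were Tff1 (−3.60 [−3.91, −3.30]), Mef2c (−2.95 [−3.24, −2.66]), Cxcl2 (−2.82 [−3.24, −2.42]), Ctse (−2.16 [−2.38, −1.94]) and the enkephalin precursor gene Penk (−2.06 [−2.22, −1.89]). T cell exhaustion genes stayed near even (median −0.10 [−0.15, −0.02], percentile 8.48), with Pdcd1, the PD-1 gene, at −0.38 and Eomes at −1.79, while naive and memory genes had a median of 0.53 [0.30, 0.79]. Type I and type II interferon medians were 0.33 [0.26, 0.38] and 0.38 [0.31, 0.50] in CD8 T cells, with 10 of 46 and 10 of 25 genes higher. Subclusters differed in weight: subcluster 0, led by Styk1, held 11 WT and 429 KO cells, and subcluster 6, led by Ndufa4 itself, 185 WT and 35 KO cells. Neutrophil markers summed to 60.3 CPM in WT and 9.82 CPM in KO CD8 T cells.

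In NK cells, Ccl4, a chemokine gene, stood at 113 and 775 CPM (2.78 [2.504, 3.07]), and 5 of 6 inflammatory mediators were higher (median 1.48 [1.17, 1.74]). Cxcl10 (3.37 [2.23, 4.82]), Nr4a2 (2.40 [1.98, 2.85]), the phosphatase gene Dusp1 (2.13 [1.76, 2.51]) and Ly6a (2.48 [1.69, 3.40]) were higher as well. Lower genes were Ctse (−2.43 [−2.83, −2.02]), Txnip (−1.60 [−1.76, −1.44]), the interleukin 7 receptor gene Il7r (−1.51 [−1.75, −1.27]), Gzmc (−1.33 [−1.43, −1.22]) and Inpp4b (−1.63 [−2.05, −1.20]). Their type I and type II medians were 0.16 [0.09, 0.31] and 0.44 [0.23, 0.52], against 0.09 and 0.22 over list members of at least 100 CPM, and the type I median was 0.022 with thinning to 1000 UMIs. With thinning to 1000 UMIs, Ly6a stood at 1.26 and Gzmc at −0.69. Cluster 2 held 137 WT and 598 KO NK cells and cluster 17, led by Gzma and Cma1, 12 and 149, and the ratios were not corrected for this mix. Neutrophil markers were at 103 CPM in WT and 14.4 CPM in KO NK cells.

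Regulatory T cells, which restrain other lymphocytes, had 16 of 26 type II interferon genes higher (median 0.80 [0.65, 0.86]) and a type I median of 0.34 [0.27, 0.46]. Cxcl10 stood at 5.92 and 153 CPM (4.69 [3.64, 6.02]) and the growth factor gene Areg at 15.2 and 273 CPM (4.16 [3.49, 4.93]). Fos (2.33 [1.88, 2.82]), Rgs2 (2.19 [1.85, 2.56]), Iigp1 (1.97 [1.77, 2.18]) and the interleukin 10 gene Il10 (1.59 [1.23, 1.97]) were also higher. Spp1 (−4.55 [−5.23, −3.93]), Ctse (−2.46 [−2.94, −2.00]), AA467197 (−1.94 [−2.47, −1.42]), Txnip (−1.82 [−2.01, −1.62]) and Ndrg1 (−1.76 [−2.21, −1.30]) were lower, and 4 of 13 hypoxia genes were lower (median −0.39 [−0.60, −0.29]). The class held 142 WT and 253 KO cells, with Spp1 at −1.38 under a mitochondrial limit of 5%, and their red pulp macrophage markers summed to 80.4 and 29.5 CPM.

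The remaining KO tumour neutrophils carried more granule and interferon-response transcripts than the WT neutrophils. Genes of the granules that neutrophils make while they mature in the bone marrow led: Camp stood at 1.98 CPM in WT and 1184 CPM in KO (9.23 [8.17, 10.54]), Ngp at 5.65 and 1577 CPM (8.12 [7.49, 8.84]) and Ltf at 18.6 and 488 CPM (4.71 [4.32, 5.12]). With equal weight for each cell these were 7.56, 6.42 and 2.855. In the granule list 9 of 12 genes were at least 1.5-fold higher and 0 lower (median 1.41 [1.12, 1.62]), with the median at 0.31 when each cell had equal weight and at 0.074 after thinning to 1000 UMIs. Of 46 type I interferon genes 40 were higher (median 1.06 [0.97, 1.17]), and of 14 type II genes 11 were higher and 1 lower (median 2.97 [2.71, 3.17]), with Gbp2 at 41.2 and 771 CPM (4.22 [3.95, 4.5045]) and Igtp at 3.53 [3.12, 3.94]. The type II median was 0.65 when each cell was thinned to 1000 UMIs.

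All 15 measured MHC class I genes were higher in these neutrophils (median 1.93 [1.71, 2.15]), and all 13 mitochondrial DNA genes were lower (median −1.36 [−1.44, −1.24]). The median mitochondrial share of a cell was 1.35% in WT and 0.370% in KO. Hspa1b (−4.94 [−6.82, −3.57]), Csta2 (−3.07 [−4.71, −1.83]), Cxcl3 at 6869 and 1082 CPM (−2.67 [−2.78, −2.55]), Rab44 (−2.60 [−3.57, −1.78]) and the thrombospondin gene Thbs1 (−2.21 [−2.35, −2.06]) were lower. With thinning to 1000 UMIs, Csta2 stood at −1.64 and Rab44 at −4.32, and with doublets kept Rab44 stood at −1.76. The median of all genes lay at 0.15 in this class, and at −0.22 in tumour B cells. Clusters 4, 8 and 14 held 54.9%, 32.1% and 13.1% of WT and 45.6%, 25.9% and 28.5% of KO neutrophils. Summed erythroid markers were 2505 CPM in WT (8662 of 8869 UMIs in 1 barcode) and 43.1 CPM in KO neutrophils, and summed NK cell markers 17.5 and 126 CPM.

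Dendritic cells of the KO tumour had higher interferon-response and cell cycle genes and lower hypoxia and suppressive genes. Il12b, a subunit gene of the T cell stimulating cytokine interleukin 12, stood at 55.9 and 227 CPM (2.02 [1.85, 2.20]), and Cxcl9 at 344 and 883 CPM (1.36 [1.29, 1.44]). Of 31 type II genes 26 were higher (median 0.97 [0.86, 1.05]) and of 61 type I genes 13 were higher (median 0.38 [0.33, 0.42]), with 0 lower in either list. By subset the type I medians were 0.69 [0.65, 0.77] in type 2 conventional and −0.19 [−0.28, −0.06] in migratory dendritic cells, the latter at a percentile of 0.01 and turning to 0.10 when each cell had equal weight. Cell cycle genes were higher in 15 of 25 cases (median 0.65 [0.55, 0.77]). Hypoxia genes were lower in 8 of 15 cases (−0.63 [−0.76, −0.45]) and suppressive and repair genes in 8 of 15 cases (−0.72 [−0.81, −0.60]), with 1 higher in the latter. MHC class II genes had a median of −0.19 [−0.20, −0.16], with 1 of 12 lower. With doublets kept, Il12b stood at 1.36 and Top2a at 1.14. Ppfia4 (4.38 [3.48, 5.46]), Egr3 (2.43 [2.12, 2.75]), Top2a (2.29 [1.99, 2.59]), Fosb (2.18 [2.05, 2.31]), Fos (2.13 [2.05, 2.21]) and Ccl4 (1.86 [1.63, 2.09]) were higher. Cxcl3 (−7.63 [−9.26, −6.40]), Spp1 (−4.69 [−4.93, −4.47]), Cxcl2 (−4.03 [−4.33, −3.75]), Hspb1 (−3.56 [−4.05, −3.11]) and Thbs1 (−3.35 [−3.70, −3.02]) were lower. Without a mitochondrial limit, Cxcl3 stood at −4.415, Cxcl2 at −2.27 and Thbs1 at −2.23. Cluster 22, led by Serpinb2, Spp1 and Cxcl3, held 6 WT and 0 KO dendritic cells. In the class as a whole, neutrophil markers summed to 96.9 CPM in WT and 17.2 CPM in KO, and NK cell markers to 13.6 and 66.5 CPM.

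Tumour B cells had a type II median of 1.36 [0.98, 1.53], with 8 of 9 genes higher, and a type I median of −0.22 [−0.40, −0.07]. Their libraries differed in the RNA of other cells, with erythroid markers at 9007 CPM in WT (9481 of 9519 UMIs in 2 barcodes) and 13.02 CPM in KO and neutrophil markers at 5990 and 91.1 CPM. Further B cell genes are therefore not listed.

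In the spleen, the KO library held fewer monocytes and more NK cells. Monocytes, sorted through CD11b, made up 35.4% of WT (2518 cells) and 18.1% of KO cells (1221 cells), a difference of −17.3 points [−18.7, −15.8]. NK cells made up 16.3% (1159 cells) and 35.8% (2418 cells), a difference of 19.5 points [18.1, 20.9]. Neutrophils made up 31.9% and 26.02% (−5.89 points [−7.40, −4.38]), dendritic cells 6.76% and 5.71% (−1.04 points [−1.85, −0.238]), and red pulp macrophages, which clear old red cells, 3.92% and 3.69% (−0.233 points [−0.871, 0.406]). T cells made up 1.10% and 3.24% (2.15 points [1.67, 2.64]), B cells 2.79% and 4.16% (1.36 points [0.755, 1.98]) and plasma cells 0.576% and 1.35%. With a mitochondrial limit of 5% the T cell difference was 0.5002 points, the B cell difference 0.032 points and the dendritic cell difference −2.07 points. With a limit of 20% the red pulp macrophage difference was 0.708 points, and without a limit 0.702 points, with the B cell difference then at 2.30 points. Many lymphocytes lack CD11b, so the gate bears directly on these shares, most of all for T, B and plasma cells.

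Spleen monocytes of the KO library had modestly higher interferon-response genes. Of 60 type I genes 13 were at least 1.5-fold higher and 0 lower (median 0.35 [0.34, 0.39], percentile 100), and of 20 type II genes 5 were higher and 0 lower (median 0.33 [0.28, 0.41], percentile 100). The type II median was 0.19 over list members of at least 100 CPM. Clusters 1, 2 and 6 held 983, 849 and 686 WT and 365, 484 and 372 KO monocytes, and these medians were not corrected for this mix. Isg15, a ubiquitin-like interferon product, stood at 24.2 and 56.1 CPM (1.21 [1.05, 1.37]) and Ifit3 at 1.06 [0.84, 1.29]. After thinning to 2000 UMIs, spleen monocytes averaged 17.4 type I list UMIs in WT and 22.01 in KO (104.9 and 112 UMIs without thinning), with 26 and 14 cells left out. The MHC class I median was 0.18 [0.15, 0.21] and the glycolysis median −0.17 [−0.22, −0.14], with no member 1.5-fold apart in either list. The largest ratio of the named genes was that of Ppfia4, from 17 UMIs in WT to 1069 UMIs in KO (7.24 [6.56, 8.03]). Atp2b4 (1.42 [1.18, 1.65]) and Ly6a (1.18 [0.94, 1.41]) were also higher. Ctse, the cathepsin E gene, stood at 108 and 22.2 CPM (−2.28 [−2.47, −2.10]). Wfdc21 (−1.94 [−2.21, −1.68]), Chil1 (−1.82 [−1.96, −1.68]), the glucocorticoid-responsive gene Fkbp5 (−1.77 [−1.89, −1.65]) and Cxcl9 (−1.27 [−1.68, −0.89]) were also lower. NK cell markers summed to 42.9 CPM in WT and 104 CPM in KO monocytes.

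Spleen neutrophils of the KO library carried more transcripts of immature stages. Granule genes were higher in 11 of 13 cases (median 1.92 [1.90, 1.95]), with Camp at 2909 and 18111 CPM (2.64 [2.62, 2.66]) and Ltf at 1556 and 10414 CPM (2.74 [2.71, 2.77]). The progenitor gene Myb (3.17 [2.67, 3.71]), Acvrl1 (3.102 [2.64, 3.6003]) and Fcnb (2.94 [2.73, 3.15]) were higher too, at 1.47, 2.37 and 3.80 with thinning to 1000 UMIs. Cell cycle genes were higher in 28 of 31 cases (median 2.41 [2.31, 2.54]), but their median was −0.015 with at least 500 genes and 1000 UMIs required per cell, 0.11 with listed genes allowed in the clustering, and at most 0.04 with doublets kept or without a mitochondrial limit. Inflammatory mediators (median −0.84 [−0.91, −0.78]) and immediate early genes (−0.95 [−0.98, −0.90]) were lower in 9 of 10 and 13 of 18 cases, with medians of −0.23 and −0.26 when each cell had equal weight. Fkbp5 (−2.44 [−2.61, −2.29]), Pik3ip1 (−2.44 [−2.88, −2.02]), Amz1 (−2.22 [−2.54, −1.92]), Cyb5r1 (−2.15 [−2.27, −2.04]) and Dusp16 (−1.81 [−2.04, −1.59]) were lower. Cluster 11, led by Ltf, and cluster 20, led by Fcnb, held 1.98% and 0.396% of WT and 17.0% and 3.75% of KO neutrophils, while clusters 0, 5 and 7 held 45.8%, 28.7% and 23.1% of WT and 27.6%, 25.5% and 26.2% of KO. Summed progenitor markers were 26.3 and 771 CPM, and the median of all genes lay at −0.15. The type I and type II interferon medians were −0.38 [−0.44, −0.31] and −0.53 [−0.66, −0.39]; both turned with equal weight for each cell, to 0.16 and 0.01, and with thinning to 1000 UMIs, to 0.18 and 0.038.

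Spleen NK cells differed little in expression despite their larger share. Their type I median was 0.01 [−0.02, 0.07] and their type II median 0.13 [0.06, 0.18], and Ifng stood at 71.4 and 73.4 CPM (0.04 [−0.14, 0.22]). Cd55, which encodes a complement inhibitor, stood at 16.9 and 65.4 CPM (1.95 [1.63, 2.29]), and the chaperone genes Hsph1 (1.07 [0.87, 1.27]), Stip1 (0.83 [0.65, 1.00]) and Hsp90ab1 (0.62 [0.57, 0.67]) and the peptidase gene Rnpep (0.92 [0.62, 1.23], but 0.11 with doublets kept) were higher. Ctse (−2.64 [−2.87, −2.42]), Hist1h2ap (−2.24 [−2.59, −1.89]), Wdfy1 (−0.95 [−1.13, −0.77]) and Gstp1 (−0.90 [−1.24, −0.56]) were lower. Plasma cell markers summed to 167 and 286 CPM in these cells. Type I and type II medians were 0.44 [0.33, 0.51] and 0.38 [0.27, 0.53] in red pulp macrophages, −0.08 [−0.14, −0.04] and −0.14 [−0.24, −0.03] in dendritic cells, 0.03 [−0.05, 0.13] and −0.05 [−0.23, 0.12] in B cells, and 0.01 [−0.08, 0.15] and 0.16 [−0.12, 0.24] in T cells. With doublets kept, the dendritic cell medians turned to 0.058 and 0.092. Erythroid markers in red pulp macrophages summed to 4820 CPM in WT and 519 CPM in KO.

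Set side by side, the interferon lists were farther from 0 in the tumour than in the spleen for monocytes, NK cells, dendritic cells and neutrophils. For monocytes, the type II median was 1.67 [1.53, 1.86] in the tumour and 0.33 [0.28, 0.41] in the spleen, and the type I median 0.81 [0.72, 0.87] and 0.35 [0.34, 0.39]. The monocyte classes were not matched between the organs. That of the tumour was cluster 6 alone, led by Ace and Adgre4. That of the spleen pooled clusters 1, 2 and 6, led by Cd300e, Plac8 and Vcan. For NK cells, the log2 ratio of Ifng was 1.94 in the tumour and 0.04 in the spleen. Neutrophils had more granule transcripts in the KO library of both organs. The NK share was higher and the phagocyte share lower in KO in both organs, whereas the B cell share was lower in the tumour (−2.65 points) and higher in the spleen (1.36 points). These differences between organs were not tested, and the sorts differed, since the spleen gate required CD11b.

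Genes that differ between C57BL/6 substrains or sexes were compared as a check of the animals' background. Nnt stood at 3.53 CPM in WT and 2.9003 CPM in KO tumour cells, and at 6.53 and 7.95 CPM in the spleen. Wdfy1 was lower in KO in both organs, at 52.5 and 29.5 CPM in the tumour and at 51.5 and 34.04 CPM in the spleen. Ide stood at 52.2 and 58.4 CPM in the tumour and 80.3 and 69.1 CPM in the spleen, and Nlrp12 at 3.81 and 0.605 CPM and at 43.2 and 34.5 CPM. These levels cover all cells of a library, so differences in class shares enter them. Nlrp12 was among the top genes of spleen neutrophil cluster 5, and neutrophils made up 26.3% of WT and 3.57% of KO tumour cells. Wdfy1, however, was also lower in KO within spleen NK cells alone, as given above. Class shares do not account for that difference, and a difference in substrain between the pools stays open. Entpd4 gave 0 UMIs in all 4 libraries. The Y-linked gene Ddx3y was present in each library, at 76.2 and 94.0 CPM in the tumour and 125 and 139 CPM in the spleen, and Xist gave at most 12 UMIs in a library; the labels name male mice. Of the 1658 genes measured in all 15 compared classes, only Ndufa4 was at least 2-fold apart in the same direction in every class. Among genes measured in at least 5 classes but not in all, Ppfia4 (5 classes, median log2 5.32), Ngp (6 classes, 2.97) and the unnamed gene model Gm42047 (5 classes, −1.85) were also at least 2-fold apart in the same direction in every class where they were measured. Ngp is a neutrophil granule gene, and summed neutrophil markers, which include it, were also higher in KO spleen monocytes (828 and 1139 CPM), NK cells (483 and 786 CPM) and dendritic cells (642 and 1146 CPM), so its ratios there cannot be assigned to those cells.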

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

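The tests of explanations in this part, except the one on cell calling, and the mitochondrial limits of 20% and none were chosen only after the result was seen. Several results lay in opposite directions in the tumour and the spleen under the same contrast, and that difference was not tested for any of them. The B cell share differed by −2.65 points in the tumour and 1.36 points in the spleen. The dendritic cell share differed by 1.30 and −1.04 points, and the monocyte share, over classes not matched between the organs, by 1.71 and −17.3 points. Without a mitochondrial limit the tumour values turned to −0.0147 and −0.00062 points, and with a limit of 20% that of monocytes was −0.32. In neutrophils, the type I interferon median was 1.06 in the tumour and −0.38 in the spleen, the type II median 2.97 and −0.53, and Cd274 0.48 and −0.81, the latter at −0.012 with equal weight for each cell. The spleen medians of both lists turned, to 0.16 and 0.009998 with equal weight and 0.18 and 0.038 with thinning to 1000 UMIs, where the tumour type II median was 0.65. In dendritic cells, the type I median was 0.38 and −0.08, the type II median 0.97 and −0.14, and Cxcl9 1.36 and −2.65. These spleen medians also turned, type I in 5 other settings (0.0051 to 0.058) and type II in 6 (0.0152 to 0.13). Other signals came from cells outside the comparisons. Melanoma-like barcodes made up 1.40% of WT and 0.542% of KO tumour cells despite the CD45 sort, and those of the KO tumour held Ndufa4 at 1284 CPM. Erythroid cells made up 0.744% of WT and 0.207% of KO spleen cells, a difference of −0.537 points, which ranged from −0.272 with a mitochondrial limit of 5% to −1.43 with one of 20%.

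The lower neutrophil share of the KO tumour was weighed against 3 technical explanations. Without a mitochondrial limit the difference was −21.6 points, 95.1% of its main size, which argues against that limit as the cause. Only 1.77% of WT tumour neutrophils held fewer UMIs than the first percentile of the KO barcodes, which argues against a loss in cell calling. Cluster 14, the tumour neutrophil cluster nearest in expression to WT spleen neutrophils (r = 0.894 across genes, which are not independent), held 10.7% of the difference, but blood itself was not sampled and erythroid marker UMIs over the tumour library were 32.6 per cell in WT and 0.478 in KO, with 106728 and 2 UMIs in melanoma-like barcodes and 9519 and 10 UMIs in B cells, so blood in the WT sample stays open. A difference between the pools in tumour size, dissociation or sorting, and the genotype itself, stay open and were not tested.

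The higher interferon lists of the KO tumour phagocytes were weighed in the same way. With the KO clusters weighted to the WT cell mix, the type II median was 1.80, or 92.4% of its main value, which argues against a shift between these clusters as the whole cause. T and NK cell markers were 40.9 CPM in WT and 173 CPM in KO phagocytes, 1.01% of the difference that RNA of those cells would need to account for the type II list. Interferon gamma made by T and NK cells may be a candidate explanation: Ifng UMIs per cell over the tumour library were 0.266 in WT and 2.34 in KO (log2 3.13 [3.04, 3.23]). A direct effect of Ndufa4 loss within phagocytes stays open as well, and no test here separates the 2, since Ndufa4 transcripts were far lower in every compared immune class of the KO mice. A difference between the pools in tumour size, dissociation, sorting or genetic background also stays open and was not tested.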

How the results depend on the processing

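The mitochondrial limits of 20% and none, and the other Leiden seed, were chosen after seeing the data. Over 295 reported results, 3851 values were computed under other settings. Of these, 3320 lay within the counting interval of the reported value, 511 lay outside it without turning a called direction (329 nearer to 0 and 182 farther from it), and 20 turned. None of the 2349 values of reported single genes turned, but these genes were named for bounds far from no difference; over everything that the naming rule covers, 156 of 34617 values turned, 95 of them of single genes. Reported gene ratios moved by over 1.5-fold in 98 values (73 nearer to 0), 49 of them with thinning. For the main results, 32 of 32 values lay within the interval at Leiden resolution 0.5, at 2.0 and with the other seed, and 25 of 25 with totals without mitochondrial, ribosomal and haemoglobin genes. Fewer did so in other settings, among them 10 of 25 with thinning to 1000 UMIs and 17 of 25 with equal weight for each cell. In each of these, 2 values turned. The count was 10 of 16 over list members of at least 100 CPM and 25 of 32 with doublets kept. No paired analysis was possible because each group is 1 pooled library. Lists left with under 4 measured members were not computed, mostly under thinning and the floor of 100 CPM. These included some lists of spleen red pulp macrophages at Leiden 0.5. With the 5% limit, tumour B cells and spleen red pulp macrophages, B and T cells fell under 50 cells in a library and were not computed. For every value below, the cause was not tested.

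In KO spleen neutrophils Ndufa4 had 0 UMIs under every setting, so its values are bounds, with −7.79 as the reported one. With at least 500 genes and 1000 UMIs per cell, this bound was −7.33, the type I and II interferon medians of spleen neutrophils −0.19 and −0.37, and their cell cycle median −0.0152; the spleen dendritic cell medians were 0.028 and 0.0596. With doublets kept, the bound was −7.42; type I medians were −0.062 in spleen NK cells, 0.34 in spleen monocytes, −0.18 in spleen neutrophils, 0.93 in tumour neutrophils and 0.058 in spleen dendritic cells, and type II medians 0.28, −0.38 and 0.092 in spleen monocytes, neutrophils and dendritic cells. With listed genes allowed in the clustering, the bound was −7.38; type I medians were −0.20 in spleen neutrophils, 0.32 in tumour dendritic cells and 0.0504 in spleen dendritic cells, whose type II median was 0.13 there and 0.044 at Leiden resolution 2.0.

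With each cell thinned to 1000 UMIs, the Ndufa4 bounds, from 0 KO UMIs, were −5.285 in spleen and −0.95 in tumour neutrophils, and its ratios −5.46 in CD8 T cells, −5.77 in tumour NK cells, −4.16 in tumour dendritic cells, and −4.98 in mononuclear phagocytes, whose complex IV median was −0.031. Type I medians were 0.18 in spleen neutrophils, 0.41 in CD8 T cells, 0.022 in tumour NK cells, 0.48 in tumour dendritic cells, 0.87 in tumour neutrophils and 0.052 in spleen dendritic cells, and type II medians 0.038, 0.79 and 0.65 in spleen neutrophils, tumour dendritic cells and tumour neutrophils. With equal weight for each cell, Ndufa4 was −6.77 in CD8 T cells, −4.46 in tumour dendritic cells and −4.90 in mononuclear phagocytes; type I medians were 0.16 in spleen neutrophils, 0.47 in tumour, 0.0051 in spleen and 0.10 in migratory dendritic cells, and type II medians 0.009998 in spleen neutrophils, 0.51 in CD8 T cells and 2.11 in mononuclear phagocytes. The log2 ratio of the median type I UMIs per thinned phagocyte was 1.32.

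Centred on the median gene, type I medians were −0.24 in spleen neutrophils, 0.91 in mononuclear phagocytes and 0.91 in tumour neutrophils, and the type II median of spleen neutrophils was −0.39. Over list members of at least 100 CPM, type I medians were 0.23 in CD8 T cells, 0.088 in tumour NK cells and 0.99 in mononuclear phagocytes, and type II medians 0.19 in spleen monocytes, 0.22 in tumour NK cells and 0.855 in tumour dendritic cells. With members of at least 5 CPM, the type II median of tumour neutrophils was 2.61. With a mitochondrial limit of 20%, the tumour NK share differed by 11.2 points and the monocyte share by −0.32 points, and the type II median of spleen dendritic cells was 0.0152; with 5%, the spleen NK share differed by 21.2 points and that median was 0.025. Without a limit, the Ndufa4 bound of spleen neutrophils was −7.34, their medians −0.19 and −0.38, and tumour shares differed by 13.15 points (CD8 T cells), 9.28 (NK cells), −0.0147 (dendritic cells) and −0.00062 (monocytes).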

Other observations

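The tests on chromosome 1 were chosen only after the result was seen. Plasmacytoid dendritic cells, known for making type I interferon, were few in the tumour, with 78 WT and 91 KO cells. Among the named genes higher in KO were the chemokine genes Ccl4, at 115 and 2028 CPM (4.14 [3.85, 4.44]), and Ccl3 (4.14 [3.06, 5.48]). So were the early response gene Fos (3.46 [3.12, 3.81]) and the transcription factor gene Klf2 (2.52 [2.13, 2.93]). Tent5c gave 1 UMI in WT and 133 UMIs in KO (6.68 [4.18, 11.99]), and with thinning to 1000 UMIs, where WT had 0 UMIs, a bound of 2.42. All 4 measured inflammatory mediators were at least 1.5-fold higher (median 2.66 [2.17, 2.88], but 0.9995 with doublets kept, where Ccl3 stood at 1.18), as were 6 of 9 type II interferon genes (median 0.94 [0.68, 1.14]), while the type I median was 0.18 [0.06, 0.30]. Of 13 cholesterol synthesis genes 9 were lower (median −0.82 [−0.94, −0.64]), including Hmgcs1 (−1.23 [−1.43, −1.02]). Scd2 (−1.06 [−1.36, −0.77]), Txnip (−0.995 [−1.28, −0.72]) and Fkbp5 (−1.49 [−2.08, −0.91]) were also lower. T cell markers summed to 41.3 CPM in WT and 104 CPM in KO cells of this class.

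A pair of genes on chromosome 1, Ctse (131638306 to 131675505) and Ppfia4 (134296783 to 134332928), stood apart in every spleen class where they were measured. The spleen medians were −2.28 over 7 classes for Ctse and 6.28 over 2 classes for Ppfia4, and the tumour medians −1.96 over 8 and 4.38 over 3 classes; Cd55 (spleen median 1.33), Chil1 (−1.18), Atp2b4 (−0.28) and Cyb5r1 (−0.31) of the same window were also apart in some class, but not in all. A stretch of DNA from another strain, carried with the Ndufa4 allele or apart from it, is a candidate explanation, although Ndufa4 lies on chromosome 6. Both genes, 100% of the 2 apart in the window from 130 to 135 Mb, kept their direction in the tumour, against 70.5% (43 of 61) of such genes elsewhere; 2 genes are too few to decide. Of the other 277 windows, 6.498% had as high a share of genes apart as the 2 of 30 here, so a chance position cannot be told apart from such a stretch.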
